A study of Homo sapiens with 4 samples.

How the data were processed

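Cultured human vascular smooth muscle cells (HCASMs in the labels) were transduced with an adenovirus that carries MYOCD or with an empty control adenovirus, and RNA was taken after 3 days. Libraries were made from 200 ng of total RNA by oligo-dT selection and strand-marked cDNA synthesis, per the labels' protocols. The stated depth was 20000000 reads per replicate, per the labels, and the totals of these libraries were not analysed here. There were 2 groups of 2 libraries. Nothing states whether the 2 libraries of a group came from separate cultures or donors, so p-values measure only the spread between these libraries, which may be technical.

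The deposited table gives FPKM values made by the authors, 1 column per library, for 214 transcript models with IDs of the form given by Cufflinks. FPKM counts fragments relative to transcript length and to the mapped fragments of the library. The denominator and any scaling between libraries are not given in the sources used here. TopHat and Cufflinks are named in the submitters' processing notes, with hg19 as the build and with no versions, roles or order. A second deposited file, whose name calls its entries lncRNAs, gives the exons of the same models. All 214 models had the same coordinates, strand, exon number and exonic length in both files. How these 214 models were chosen is not given in the sources used here. Every model had at least 2 exons, and the smallest of the models' highest values was 0.352 FPKM. No model was at 0 in every library.

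Groups were taken from the sample titles, which match the transduction labels. The free-text descriptions of the same samples say the reverse: the control samples are described as MYOCD overexpression and the MYOCD samples as empty virus. The table has no row for the MYOCD gene, so its level could not be used to check the labels. The libraries are therefore called empty virus and labelled MYOCD, and each direction given holds only if the titles are right.

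Values were tested on the log2(FPKM + 1) scale with limma 3.58.1 in R 4.3.3, with an empirical Bayes trend on the mean level and no covariate. P-values were two-sided and adjusted by Benjamini-Hochberg over the 214 models, with a threshold of 0.05. Differences on this scale understate the change of models with low values. A value of 0 in this table can be a failed or divided estimate and is described as listed at 0, with no fold given against a group at 0. An exact permutation test of 2 libraries against 2 cannot go below a two-sided p of 0.33. Models whose spans overlapped by at least 1 base on the same strand were joined into 175 loci, and their FPKM values were summed and tested in the same way. That step was chosen after seeing the data.

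The number of reads behind each value is unknown. Ratios between the values of 1 model in different libraries were searched for steps of whole reads, in models alone in their locus. Of 136 ratios between 1.5 and 6.5, 11.8% lay within 0.05 of a whole number, where chance gives 10%, so reads could not be recovered. At the stated 20000000 reads and full exonic length, 1 read would be worth 0.109 FPKM for the median length of 460 bases, 0.42 FPKM for the shortest model of 119 bases and 0.00935 FPKM for the longest of 5346 bases. These nominal figures ignore the effective length that Cufflinks can use, which is shorter than the model.

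The test was checked on 20 simulated sets of 214 models, drawn as over-dispersed reads at the empty virus levels, in which 60 models changed by known folds. Models were drawn at the stated depth. With the pseudocount of 1, 57% of 8-fold rises, 21.5% of 4-fold rises and 3% of 2-fold rises were called. Of 8-fold falls 20.5% were called, of 4-fold falls 11.5% and of 2-fold falls 2%. Of models with no change, 0.39% were called. The extra spread of the simulated reads was a fixed setting and was not fitted to these libraries. Some models varied more than that, such as TCONS_00000603 at 31.5 and 10.2 FPKM in the empty virus libraries. These rates may therefore not describe the test on the real values.

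Before the data were examined, the text was set to name the 12 largest differences in each direction among models whose 2 groups did not overlap, those past the threshold first. It was also set to name the 5 models with most exons and the 5 longest, with ties in order of ID. The other settings tried were pseudocounts of 0.1 and 0.01, a mean of at least 1 FPKM, median centring, no trend, a replicate block, other thresholds, and leaving out each library. Of the 11 gene lists fixed in advance (contractile smooth muscle, SRF cofactors and regulators, immediate early SRF targets, cardiac and skeletal muscle, cell cycle, matrix and synthetic state, inflammation and interferon, known long noncoding RNAs, endothelial cells, blood and immune cells, and fibroblasts and pericytes), 0 had a member in the table by name, so no list was tested. The files do not pair the model IDs with gene names, and 0 of the 214 IDs were found in the reference tables of gene names, so models are given by ID and position. An hg19 gene annotation was not used here, so the models were not assigned to neighbouring genes, introns or UTRs. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 in Python 3.11.15.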

Results

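The data were FPKM values of 214 lncRNA transcript models in 4 polyadenylated RNA-seq libraries of cultured human vascular smooth muscle cells, 2 transduced with an empty adenovirus and 2 labelled as transduced with MYOCD. MYOCD encodes myocardin, a coactivator of serum response factor that turns on smooth muscle genes. The comparison asks which of these RNAs differed in level after MYOCD was overexpressed. The models fell into 175 loci on hg19, of which 32 held 2 or more overlapping models. Of the models, 158 had 2 exons, 39 had 3 exons and 17 had 4 to 7 exons, and 108 lay on the plus strand and 106 on the minus strand. Exonic length ran from 119 to 5346 bases with a median of 460 bases, and 15 models were under 200 bases. The name lncRNA is that of the submitters. The sample titles and the free-text descriptions of the samples contradict each other on which group received MYOCD, and directions below follow the titles. Levels were low, with a mean of at least 1 FPKM over the 4 libraries in 69 models and of at least 10 FPKM in 8.

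The libraries differed in how many models were listed at 0. In the empty virus libraries 42 (19.6%) and 37 (17.3%) of the 214 models were at 0, and the median FPKM was 0.734 and 0.743. In the libraries labelled MYOCD 84 (39.3%) and 79 (36.9%) were at 0, and the median FPKM was 0.196 and 0.216. Across models, which are not independent replicates, log2(FPKM + 1) correlated with a Pearson r of 0.74 between the libraries labelled MYOCD and of 0.60 between the empty virus libraries. Between groups, r lay between 0.40 and 0.49. By rank the agreement was weaker, with a Spearman rho of 0.55 between the libraries labelled MYOCD and 0.33 between the empty virus libraries. Between groups, rho lay between 0.015 and 0.11.

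At an adjusted p under 0.05, 2 lncRNA models passed as lower in the libraries labelled MYOCD and 0 as higher. TCONS_00000644, a 2-exon RNA of 521 bases on the plus strand of chromosome 3 (156428472 to 156469653), was at 12.6 ± 1.43 FPKM with empty virus and at 0.347 ± 0.162 FPKM in the libraries labelled MYOCD (SD, n = 2 each), 36.2 times lower. Its log2(FPKM + 1) change was -3.33 ± 0.23 (SE), with an adjusted p of 0.0319 (limma, Benjamini-Hochberg). TCONS_00000144, a 2-exon RNA of 789 bases on the plus strand of chromosome 11 (8739753 to 8741333), was at 6.76 and 6.75 FPKM with empty virus. It was listed at 0 and at 0.048 FPKM in the libraries labelled MYOCD, a change of -2.92 ± 0.21 (SE) with the same adjusted p of 0.0319 in limma. A further 11 models, 4 higher and 7 lower, shared an adjusted p of 0.05003, just above the threshold of 0.05. At an unadjusted p under 0.05 there were 12 higher and 45 lower models. With a pseudocount of 0.1 in place of 1, 35 models passed, 8 higher and 27 lower. Among them were TCONS_00000644, TCONS_00000144 and 10 of those 11. With median centring 3 passed, 1 higher (TCONS_00000773) and 2 lower. Without 1 library, the lone library of a group is assumed to vary like the other group. Models at 0 in both libraries labelled MYOCD have no spread there. Leaving out library 1 or 2 labelled MYOCD left 0 models past the threshold in limma (36 and 38 at an unadjusted p under 0.05), and leaving out empty virus library 1 or 2 gave 65 or 71.

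The 2 libraries of each group did not overlap in 115 models (53.7%), where the mean over the 3 ways to split the 4 libraries into pairs was 28.7%, since the 30 models above 0 in 1 library only are tied at 0 and cannot separate. The 2 other splits gave 18.7% and 13.6%. A model can separate in only 1 of the 3 splits, so these 2 shares fall as that of the labelled split rises. Of the 115 models, 81 were lower and 34 were higher in both libraries labelled MYOCD, so 70.4% were lower (exact binomial 95% interval 61.2% to 78.6%). The interval counts models, and ignores that all models share the same 4 libraries and that models of 1 locus share reads. The median log2(FPKM + 1) difference over all models was -0.33. It was -0.22 after median centring, -0.83 with a pseudocount of 0.1, and -0.17 and -0.13 without empty virus library 1 and 2. Over the 84 models above 0 in every library, a set that leaves out all models listed at 0 in any library, it was -0.037.

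**Figure D1:**
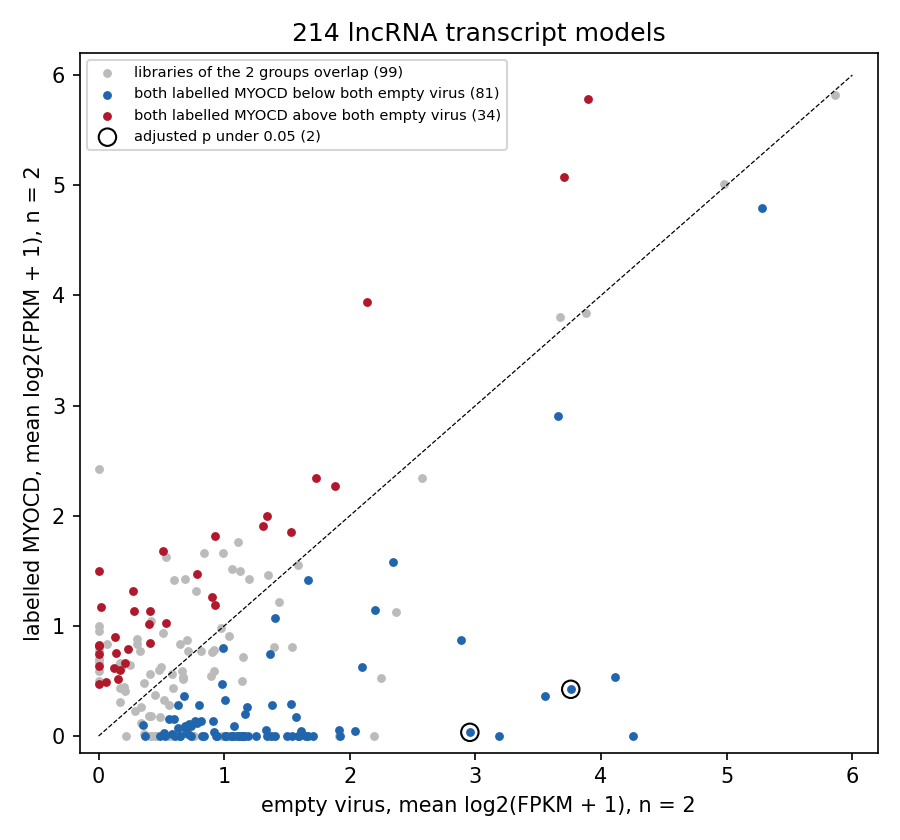
Mean log2(FPKM + 1) of each model in the 2 empty virus libraries (horizontal axis) and in the 2 libraries labelled MYOCD (vertical axis). Each point is 1 model, coloured by whether the groups overlap, circles mark the 2 models past the threshold, and 81 models lie lower and 34 higher in both libraries labelled MYOCD.

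Among the models with the largest lower differences and groups that did not overlap, several were listed at 0 in both libraries labelled MYOCD and none of the following passed the threshold with a pseudocount of 1, all 214 models, all 4 libraries and no covariate. TCONS_00000603, a short RNA of 119 bases on chromosome 22 (24790283 to 24798589), was at 31.5 and 10.2 FPKM with empty virus. TCONS_00000931, 152 bases on chromosome 7 (98739799 to 98781276), was at 17.4 and 3.52 FPKM, and TCONS_00000118, 216 bases on chromosome 10 (28367266 to 28395625), at 0.909 and 6.49 FPKM. The longer TCONS_00000651 on chromosome 3 (25567702 to 25581745) was at 2.32 and 2.21 FPKM, and TCONS_00001042 on chromosome 9 (71113252 to 71115498) at 2.38 and 1.99 FPKM. TCONS_00000722, an RNA of 3077 bases on chromosome 4 (5640715 to 5668972), was at 3.36 and 2.88 FPKM with empty virus and at 0.0578 and 0.0113 FPKM in the libraries labelled MYOCD. For TCONS_00000636 on chromosome 3 (66022324 to 66025020) the values were 2.50 and 3.04 FPKM with empty virus and 0.0847 and 0 FPKM otherwise. On chromosome 7, TCONS_00000928 (75666971 to 75670969) was at 19.9 and 13 FPKM with empty virus and at 1.10 and 0 FPKM in the libraries labelled MYOCD. TCONS_00000776 on chromosome 4 (120070957 to 120072186) was at 5.86 and 19.1 FPKM against 0.661 and 0 FPKM. TCONS_00000253 on chromosome 12 (54785614 to 54786072) was at 10.8 and 3.61 FPKM against 0.490 and 1.24 FPKM. Adjusted p in limma ran from 0.05003 to 0.215 over these 10 models.

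Among models whose groups did not overlap, the largest higher difference was that of TCONS_00000773, a 3-exon RNA on the minus strand of chromosome 4 (74566072 to 74586754). It was at 14.1 ± 3.49 FPKM with empty virus and at 54.0 ± 1.81 FPKM in the libraries labelled MYOCD (SD, n = 2 each), 3.83 times higher. TCONS_00000268, of 178 bases on chromosome 13 (41456937 to 41482300), was at 3.39 ± 0.03 FPKM with empty virus. It was 4.26 times higher, at 14.4 ± 2.11 FPKM, in the libraries labelled MYOCD (SD, n = 2 each). TCONS_00001019, of 175 bases on chromosome 8 (8761040 to 8791510), was at 12.1 ± 1.64 FPKM with empty virus. In the libraries labelled MYOCD it was at 32.7 ± 3.99 FPKM (SD, n = 2 each), 2.70 times higher. TCONS_00000191 on chromosome 11 (103738481 to 103744922) was listed at 0 in both empty virus libraries and at 1.71 and 1.93 FPKM in the others. These 4 models had an adjusted p of 0.05003 in limma. TCONS_00000738, the other model of the chromosome 4 locus (74571157 to 74586890), was at 0.389 and 0.462 FPKM against 2.14 and 2.28 FPKM. TCONS_00000296 on chromosome 14 (101538502 to 101539760) was at 0 and 0.0231 FPKM against 1.21 and 1.29 FPKM, and both it and TCONS_00000738 had an adjusted p of 0.0794 in limma. The other 6 named models, TCONS_00000585 on chromosome 21 (18984153 to 18985637), TCONS_00000109 (108371232 to 108378521), TCONS_00000135 (35894365 to 35896705) and TCONS_00000132 (105456545 to 105464344) on chromosome 10, TCONS_00000718 on chromosome 3 (156952379 to 156952840) and TCONS_00000836 on chromosome 5 (102847637 to 103269715), had adjusted p of 0.111 to 0.240 in limma. Mean levels of these 6 in the libraries labelled MYOCD were 0.767 to 2.53 FPKM.

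**Figure D2:**
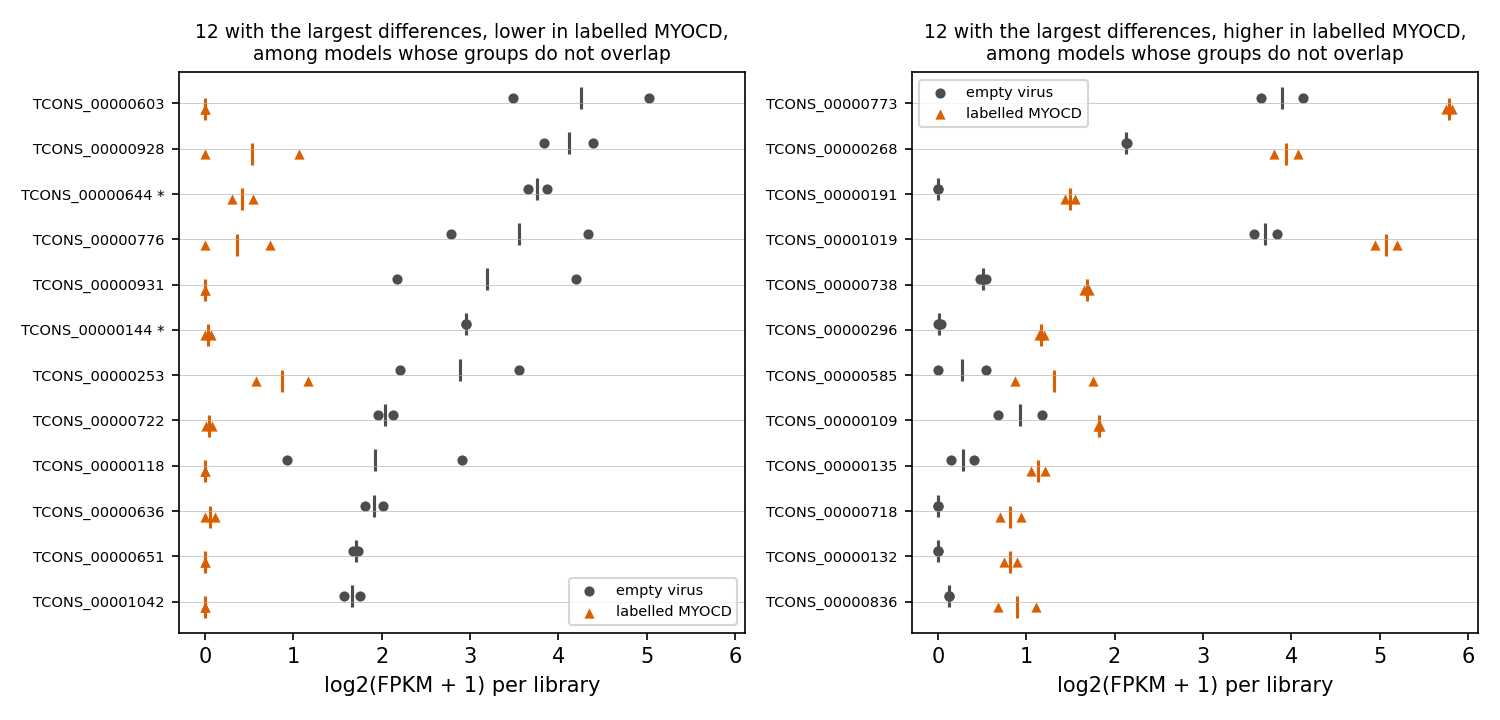
Log2(FPKM + 1) of the 12 models with the largest lower (left) and the 12 with the largest higher (right) differences, among models whose groups did not overlap. Points are single libraries, vertical ticks are means of 2 libraries, asterisks mark the 2 models past the threshold (TCONS_00000644 and TCONS_00000144), and most models of the left panel sit at or near 0 in both libraries labelled MYOCD.

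A set of 33 models was listed above 0 in both empty virus libraries and at 0 in both libraries labelled MYOCD, and 6 models showed the reverse. Divided along either of the 2 other ways to split the 4 libraries into pairs, 9 and 4 models in all had such a pattern, against 39 for the labelled groups. A model can show this pattern along only 1 of the splits, so these counts are not independent. Besides those already named, the 33 included TCONS_00000495 on chromosome 2 (120410965 to 120414132), at 1.92 and 1.90 FPKM with empty virus and with an adjusted p of 0.05003 in limma. The 33 also count TCONS_00000859 on chromosome 6, which was at 2.67 FPKM and at only 0.000184 FPKM with empty virus. The 6 models in the reverse class were TCONS_00000191, TCONS_00000132, TCONS_00000718, TCONS_00000088 on chromosome 1 (2137437 to 2138614), TCONS_00000616 on chromosome 22 (24643776 to 24644904) and TCONS_00000831 on chromosome 5 (133862364 to 133863950). The last 3 of these and TCONS_00000495 lay outside the naming rule and were chosen after their values were seen.

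With groups as titled, FPKM summed over overlapping models was tested over 175 loci, a step chosen after seeing the data. In limma with Benjamini-Hochberg over loci, 19 passed the threshold, 5 higher and 14 lower in the libraries labelled MYOCD. The minus-strand locus of chromosome 4 (74566072 to 74586890, 2 models) rose from 17 and 12.1 FPKM to 54.9 and 57.6 FPKM, a log2(FPKM + 1) change of 1.90 ± 0.19 (SE) with an adjusted p of 0.0302 in limma. The 2-model locus of chromosome 3 (156428472 to 156469653) fell from 13.0 and 14.5 FPKM to 0.233 and 0.461 FPKM, a change of -3.46 ± 0.20 (SE) with an adjusted p of 0.0231 in limma. A 4-model locus on the minus strand of chromosome 6 (118452421 to 118517056) fell from 3.92 and 3.40 FPKM to 0 and 0.00996 FPKM, with an adjusted p of 0.0302 in limma. Within that locus TCONS_00000858 was at 1.25 and 0.904 FPKM in the empty virus libraries, whereas TCONS_00000859 was at 2.67 and 0.000184 FPKM, TCONS_00000881 at 0.000799 and 1.16 FPKM and TCONS_00000882 at 0.00114 and 1.33 FPKM. Loci of 2 models each also fell on chromosome 2 (121610113 to 121622613), chromosome 9 (73028563 to 73077768) and chromosome 15 (66188168 to 66284728), all from between 1.43 and 2.52 FPKM to a listed 0 in both libraries. The 13 other loci past the threshold held 1 model each, and so had the values of that model. Among these models only TCONS_00000144 passed in the test over the 214 models. The 4 such loci higher in the libraries labelled MYOCD were TCONS_00000268, TCONS_00000191, TCONS_00000296 and TCONS_00001019. In the test over models TCONS_00000296 had an adjusted p of 0.0794 and the others of 0.05003 (limma). Leaving out either library labelled MYOCD left 0 loci past the threshold, and leaving out empty virus library 1 or 2 gave 53 or 59 loci, 16 of the 19 among them in each case.

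**Figure D3:**
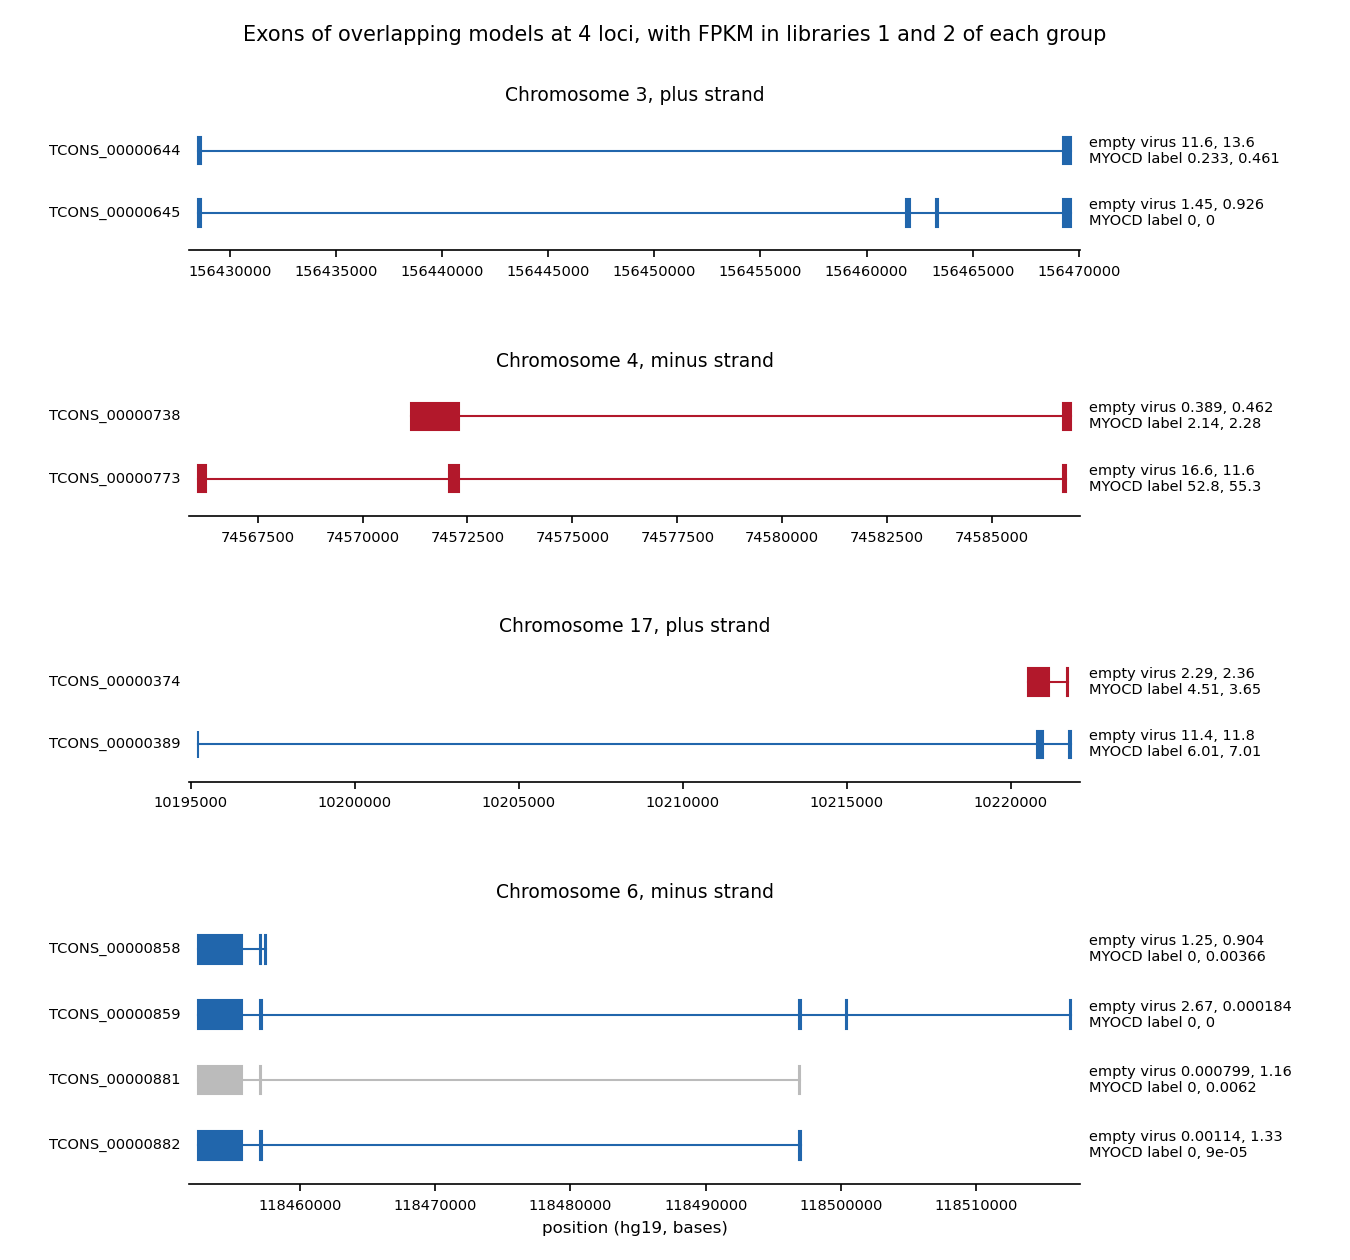
Exon maps (boxes, joined by introns as lines) of the models of 4 loci along hg19 positions in bases, with FPKM in libraries 1 and 2 of each group at the right. Blue models are lower and red models higher in both libraries labelled MYOCD, a grey model overlaps between groups, and 3 of the 4 chromosome 6 models are near 0 in 1 of the empty virus libraries.

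The models with most exons were TCONS_00000836 on chromosome 5 (102847637 to 103269715, 7 exons), TCONS_00000888 (7 exons), TCONS_00000864 and TCONS_00000889 (6 exons each) of 1 locus on chromosome 6 (136160193 to 136243395), and TCONS_00000199 on chromosome 11 (38897473 to 39183342, 5 exons). None passed the threshold, with adjusted p from 0.177 to 0.636 in limma. The sign of the difference turned for TCONS_00000864 without empty virus library 1 and for TCONS_00000889 without empty virus library 2. The longest model, TCONS_00000877 on chromosome 6 (12291486 to 12313638, 5346 bases), was at 1.58 ± 0.08 FPKM with empty virus and 0.673 ± 0.08 FPKM in the libraries labelled MYOCD (SD, n = 2 each), with an adjusted p of 0.188 in limma. The next longest were TCONS_00000259 on chromosome 13 (107142152 to 107146884) and TCONS_00000859, TCONS_00000882 and TCONS_00000858 of the 4-model chromosome 6 locus. All 4 were at 0.00366 FPKM or lower in the libraries labelled MYOCD, with adjusted p from 0.095 to 0.431 in limma.

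The 3 RNAs with the highest mean with empty virus did not pass the threshold with a pseudocount of 1 and all 4 libraries. TCONS_00000713 on chromosome 3 (96068283 to 96069684) was at 57.1 FPKM with empty virus and 55.4 FPKM in the libraries labelled MYOCD, a log2(FPKM + 1) difference of -0.04 ± 0.07 (SE) with an adjusted p of 0.672 in limma. TCONS_00000846 on chromosome 6 (34215937 to 34231418) was at 30.6 and 31.3 FPKM, a difference of 0.03 ± 0.12 (SE) with an adjusted p of 0.839 in limma. TCONS_00000760 on chromosome 4 (63682754 to 63683216) was at 37.8 FPKM with empty virus and 26.8 FPKM otherwise, a difference of -0.48 ± 0.09 (SE) with an adjusted p of 0.0794 in limma. TCONS_00000760 passed with a pseudocount of 0.1, as lower in the libraries labelled MYOCD. The difference of TCONS_00000713 changed sign with median centring and without empty virus library 1, and passed as lower without empty virus library 2, and that of TCONS_00000846 changed sign without empty virus library 2 or library 1 labelled MYOCD. These 3 models were chosen for their level after the values were seen.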

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

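The length minimum, all locus values and each combination with a pseudocount of 0.1 were tests chosen after the results were seen. The count of models past the threshold, 2 with a pseudocount of 1, was 35 with a pseudocount of 0.1, 49 with 0.01, 16 among models with a mean of at least 1 FPKM, 10 among models of at least 200 bases, 26 at an adjusted p under 0.1 and 19 when loci replaced models. Fewer features tested is part of the construction of the length, level and locus settings. The count was 2 without the trend and with a minimum log2 change of 1, and 3 with median centring. Requiring a value above 0 removed no model. Leaving out 1 library gave 0 to 71 models, where the lone library of a group is assumed to vary like the other group, and models at 0 in both libraries labelled MYOCD have no spread. With a pseudocount of 0.1 the count was 27 after centring, 48 with a replicate block, 55 and 59 without empty virus libraries 1 and 2 (0 of the first 2 models among them), and 0 without either library labelled MYOCD (46 and 53 at an unadjusted p under 0.05, limma). Of the 35 calls at that pseudocount, 20 were at 0 in both libraries of a group.

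Across models, the difference between libraries 1 and 2 on the log2(FPKM + 1) scale correlated between the groups with a Pearson r of 0.16 and a Spearman rho of 0.07. With 2 libraries per group this cannot show that the numbers pair the samples. With the replicate block 2 models passed, TCONS_00000644 and TCONS_00000928, both lower in the libraries labelled MYOCD, and TCONS_00000144 did not. The 19 loci became 0 with the replicate block (39 at an unadjusted p under 0.05, limma), 28 with a pseudocount of 0.1, 15 with median centring (5 higher and 10 lower) and 0 to 59 when 1 library was left out.

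The median log2 difference of -0.33 was negative in every setting run. It was -0.83 and -0.91 with pseudocounts of 0.1 and 0.01, -0.24 among models with a mean of at least 1 FPKM, -0.22 after centring, and -0.41 to -0.13 when 1 library was left out. With a pseudocount of 0.1 it was -0.62 after centring, -0.83 with the replicate block, -0.53 and -0.45 without empty virus libraries 1 and 2, and -1.11 and -1.08 without libraries 1 and 2 labelled MYOCD. Of the 33 models named by the rule, 2 changed sign. TCONS_00000864 ranged from -0.70 to 0.018 when 1 library was left out, positive without empty virus library 1, where it was 0.16 with a pseudocount of 0.1. TCONS_00000889 ranged from -0.56 to 0.12, positive without empty virus library 2, and with a pseudocount of 0.1 was 0.72 there and 0.060 without library 1 labelled MYOCD. Of the models named after their values were seen, 3 changed sign. TCONS_00000713 was 0.067 with median centring (0.17 with a pseudocount of 0.1) and -0.11 to 0.024 when 1 library was left out, and TCONS_00000846 -0.088 and -0.010 without empty virus library 2 and library 1 labelled MYOCD (-0.090 and -0.010 with a pseudocount of 0.1) and 0.16 without empty virus library 1. TCONS_00000881 was 0.0033 without empty virus library 2 (0.032 with a pseudocount of 0.1) and -1.11 without empty virus library 1. Beyond what the construction of a setting shows, the cause was not tested. Tests of gene lists, their camera alternatives, classes by gene annotation and count models were not run, because the table holds FPKM of unnamed models. Read number limits low values, since 1 nominal read is worth 0.109 FPKM at the median length.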

Other observations

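The tests of read number, model length, the chromosome 17 locus and other splits of the libraries were chosen after the results were seen, and those of scaling and exchanged labels before. Among 50 pairs of models in 1 locus, both models had groups that did not overlap in 12 pairs, of which 10 were lower together (3 of them pairs of the 4-model chromosome 6 locus), 1 was higher together and 1 went in opposite directions. These 3 pairs rest on TCONS_00000859 at 0.000184 FPKM in empty virus library 2 or on TCONS_00000882 at 0.00114 FPKM in empty virus library 1. Both values are below the nominal 0.00935 FPKM of 1 read on the longest model. None of the 50 pairs passed an adjusted p of 0.05 for a change in the log2 ratio of its models (limma), and 2 had an unadjusted p under 0.05. The pair in opposite directions lay on the plus strand of chromosome 17 (10195210 to 10221853). There TCONS_00000389 was at 11.4 and 11.8 FPKM with empty virus and 6.01 and 7.01 FPKM in the libraries labelled MYOCD, and TCONS_00000374 at 2.29 and 2.36 against 4.51 and 3.65 FPKM. The share of the locus FPKM from TCONS_00000374 was 16.7% in both empty virus libraries and 42.9% and 34.2% in the others. The difference in their log2 ratio between groups was 1.35 ± 0.37 (SE), with an unadjusted p of 0.025 and an adjusted p of 0.617 (limma). The summed FPKM of the locus was 13.7 and 14.1 with empty virus and 10.5 and 10.7 in the others, a log2(FPKM + 1) difference of -0.36 with an adjusted p of 0.141 (limma over loci). FPKM times length, which follows the reads of a model rather than its copies, differed over the locus by -0.084 (log2), with 4.91 and 5.06 with empty virus and 4.85 and 4.55 in the others. A different choice of exons and a different division of shared reads by the estimator may both leave that length-weighted sum nearly unchanged, so they cannot be told apart here.

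More models were lower than higher in the libraries labelled MYOCD. A difference in scaling was examined with each library scaled to 1 median over the 84 models above 0 in all 4. Of the models with groups apart, 65.2% were still lower (75 lower and 40 higher, exact binomial 95% interval 55.8% to 73.9%). Of such loci, 63.8% were lower (53.9% to 73.0%). Scaling cannot move a listed 0. The 33 models at 0 only in both libraries labelled MYOCD, and the 6 at 0 only in both empty virus libraries, kept their direction by construction. Scaling therefore stays open for the models above 0, though a factor alone does not make a value 0. The intervals given here ignore that all models and loci share the same 4 libraries. Fewer reads in the libraries labelled MYOCD stay open as a candidate explanation, since among loci with a mean of at least 20 nominal reads 62.2% were lower (23 lower and 14 higher, 44.8% to 77.5%), an interval that includes an even split, and 55.3% after scaling as well (21 lower and 17 higher, 38.3% to 71.4%). An exchange of the group labels would turn every direction given here and stays open too, because 0 rows of the table name the MYOCD gene. The unknown choice of the 214 models and an effect of MYOCD itself were not tested and also stay open.

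Of the 3 splits of the 4 libraries into pairs, 1 (the labelled one) gave as many as 2 models past the threshold, and the highest of the others was 0. For loci the labelled split gave 19 and the others 0. With 3 splits no share under 0.05 can be reached.

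Values in a single library were common. Above 0 in 1 library only were 30 models, 12 and 9 in empty virus libraries 1 and 2 and 6 and 3 in libraries 1 and 2 labelled MYOCD, with a median of 2.95 FPKM and a highest value of 27.8 FPKM there. Their median exonic length was 251.5 bases, against 519 bases for the other 184 models (two-sided permutation test with 100000 resamples, p = 0.018). Short models may gain sizeable FPKM from few reads, but the number of reads behind these values is unknown. A nominal read is worth at most 0.42 FPKM, for the shortest model, below both the median and the highest value given here. That nominal figure ignores the effective length. RNAs present in 1 library only remain possible.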
